A study of Mus musculus with 41 samples.

How the data were processed

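Gene expression was measured by poly(A) RNA sequencing in 21 libraries: 5 of sorted ex vivo microglia, 2, 3 and 5 of microglia cultured for 6 h, 24 h and 7 d, 2 cultured 7 d with TGFβ and 4 of whole brain lysate. Per the labels, RNA came from 100000 to 150000 cells, ATAC from 80000 cells and ChIP from 500000 to 2000000 cells, and cultures were kept in DMEM/F12 with 5% serum and daily IL-34. The label of 24 h replicate 2 gives 22 h and that of 7 d ATAC replicate 2 gives 8 d; both stayed in the group of their title.

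The deposited read counts are whole numbers per gene symbol for 24537 symbols in 21 libraries, and each RNA library matches a column of the table. The deposited TPM table is called trimmed by the authors, what was trimmed is not given in the sources used here, and the genes it lists sum to 568934 to 644847 per library. Other values were deposited as peak intervals, 6 lists of start and end positions: per the file headers HOMER findPeaks was run on 1 pooled tag directory per condition, against a pooled input for H3K27ac, H3K4me2 and PU.1 and without input for ATAC. The peak files used here hold no score. The processing notes name STAR, Bowtie2, HOMER, bedtools, limma, R 3.3.1, mm10 and hg38; the role of each, any adapter trimming and any shift of ATAC reads for the transposase are not given in the sources used here, and hg38 was not used here.

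Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit with robust estimation, quasi-likelihood F test), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 17 microglial libraries formed 1 model of group means, so that groups of 2 borrow the spread of the others, and the lysate comparison was fitted on its own 9 libraries. Standard errors are the log2 fold change divided by the square root of F. Group means in CPM use the effective library sizes of each model, which is why ex vivo levels differ slightly between the lysate and culture comparisons, while values of single libraries and of marker lists in CPM use total counts without TMM. A gene with 0 counts in a group is given against a floor of 3 counts over that group, and one with 1 to 3 counts as a ratio with its 95% exact Poisson interval; such bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

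The groups, tests, comparisons, gene lists and most alternatives were fixed before the data were examined. Named genes are, per comparison, 10 fixed genes (Sall1, P2ry12, Tmem119, Cx3cr1, Spi1, Csf1r, Apoe, Il1b, Mki67 and Smad7), the 5 largest rises and 5 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups' libraries, leaving out unnamed gene models, and, of each list described, up to 4 called members with the smallest adjusted p and up to 2 members not called. There were 13 gene lists and 13 lists of cell type markers, and which gene lists are described for a comparison was decided after their values were seen. Some genes that this rule selects are not reported here, and they are left out of the counts of named values under alternatives, though not of any list or count of genes called. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 104 tests, and repeated with an estimated correlation and with fry. Gapdh was counted at 0.608 to 4.20 CPM and Pgk1 at 1.26 to 30.6 CPM in every library, far below the usual level of these enzymes. The cause was not tested. Counts of genes that share reads with pseudogenes or paralogs are taken as uncertain, and Gapdh and Pgk1 are not interpreted.

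Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp, beside 20 shifts of the peaks by 1 to 10 Mb in either direction. The annotation used here holds gene bodies on mm10 without strand, so each peak was given to the nearest gene body within 100 kb and called near a gene end within 1 kb of either end, in place of the transcription start planned. Differences of median log2 fold change between gene classes were tested with 100000 permutations, 2-sided, with 95% bootstrap intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and figures were drawn with matplotlib 3.10.9. A planned test of sequence motifs was not run because no genome sequence was used here, and the 8 input libraries were not analysed here on their own.

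The procedure was tested on simulated data. With few genes changed, 1 to 7 false calls were made per comparison, and 19 to 41 by the DESeq2 test, whose calls beside an edgeR value that was not called carry this higher error. With edgeR 4-fold changes were recovered at 75.8% to 97.0% and 2-fold changes at 35.8% to 73.1%, 3 of 3 seeded lists were called and 0 of 17 others. Genes were drawn independently of each other, while the correlation estimated within the real interferon-response list at 7 d was 0.871. The simulated lists therefore cannot show how often lists of correlated genes are called falsely. The simulations took the group sizes, the depth of 11.6 to 28.8 M counts (M, 1e6) and the dispersions of these libraries (pairwise correlations within groups of 0.945 to 0.993) without varying any of them, and 1.5-fold changes were recovered at 4.5% to 29.9%. Alternatives comprised DESeq2 1.42.0 size factors and its Wald test, no filter or at least 5 CPM, only the 2 groups compared, a replicate block, a fold change of at least 2, the deposited TPM with a pseudocount of 1 or 0.1 and with or without a filter at 1, and leaving out each library; where this left 1 library in a group, that library was assumed to vary like the other groups. Relative to TMM, DESeq2 size factors moved the median log2 fold change of all genes by -0.28 in the lysate comparison and by -0.10 to 0.07 in the others.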

Results

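Microglia, the resident macrophages of the brain, were isolated from C57Bl6 mice by flow cytometry as live CD11b+ CD45Low cells. They were profiled directly (ex vivo) or after culture with IL-34, a ligand of the CSF1 receptor, for 6 h, 24 h or 7 d. A further 7 d culture received IL-34 together with TGFβ, a cytokine that microglia meet in the brain. The 41 samples comprised 21 RNA libraries, 12 chromatin libraries and 8 input libraries. Poly(A) RNA was sequenced in 5 libraries ex vivo, 2 at 6 h, 3 at 24 h and 5 at 7 d, in 2 libraries cultured 7 d with TGFβ and in 4 libraries of whole brain lysate. Chromatin accessibility (ATAC) and the active mark H3K27ac were profiled ex vivo and after 7 d, and H3K4me2, a mark of enhancers and promoters, and the transcription factor PU.1 ex vivo only, with 2 libraries per group. RNA libraries held 11.6 to 28.8 M counts (M, 1e6), which was 13.3 to 21.9 M ex vivo, 21.4 to 25.6 M at 6 h, 21.3 to 21.9 M at 24 h, 24.2 to 28.0 M at 7 d, 23.9 to 28.8 M with TGFβ and 11.6 to 25.7 M in lysate. Values are CPM (counts scaled to 1e6 per library) as mean ± SD, or log2 fold changes ± standard error with edgeR adjusted p. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries.

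Sorted microglia (n = 5) were compared with brain lysate (n = 4) to show which transcripts were higher after the sort. Every one of the 24 genes of the homeostatic microglia list was higher after sorting. Cx3cr1, the fractalkine receptor, rose 239-fold from 43.8 ± 5.44 to 10500 ± 1040 CPM (log2 7.90 ± 0.18, adjusted p = 4.62e-11). The purinergic receptor P2ry12 rose 208-fold (7.70 ± 0.38), the microglial surface protein Tmem119 170-fold (7.41 ± 0.18) and Csf1r, the receptor for CSF1 and IL-34, 163-fold (7.35 ± 0.19). Siglech, a sialic acid-binding lectin, rose 148-fold (7.21 ± 0.17), Spi1, which encodes PU.1, 102-fold (6.67 ± 0.23), and Sall1, a transcription factor of microglia, 86.8-fold (6.44 ± 0.21). The interleukin gene Il1b rose 38.9-fold to 4.87 ± 1.23 CPM, Smad7, an inhibitor of TGFβ signalling, rose 5.90-fold, and the proliferation marker Mki67 rose 5.43-fold to 9.85 ± 6.16 CPM. Apoe, an apolipoprotein that astrocytes also express, fell 3.61-fold (-1.85 ± 0.46), from 755 ± 55.2 to 209 ± 164 CPM. Its ex vivo libraries held 199, 120, 475, 67.8 and 110 CPM, and without replicate 3 the log2 change was -2.61 here and, in the cultures below, -2.26 at 6 h, -3.17 at 24 h, 2.42 at 7 d and 5.14 with TGFβ. In all, 6002 genes were higher and 6673 lower of 15335 tested, and 4393 and 5589 of them by at least 2-fold.

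The largest rises on sorting were in Rgs1, a regulator of G-protein signalling (99.1 ± 106 CPM against 1 count in 4 lysate libraries), and in the cytokines Ccl2 (59.2 ± 42.8 CPM against 1 count) and Tnf (57.9 ± 59.7 CPM against 2 counts). Counting error alone puts these ratios at 1400 to 308000, 835 to 184000 and 630 to 18800 (95% Poisson intervals). The chemokine genes Ccl4 and Ccl3 rose 2450-fold and 1820-fold. The lysate was not sorted, so enrichment of microglia cannot be told apart from induction during isolation for the genes of this paragraph. Of the inflammatory list 17 of 19 genes rose and 2 fell, with Tlr2, a receptor for bacterial lipoproteins, at 182 ± 19.1 CPM (8.28 ± 0.23), the inflammasome sensor Nlrp3 at 223 ± 65.1 CPM (8.03 ± 0.35), the lipopolysaccharide co-receptor Cd14 at 343 ± 21.2 CPM (7.90 ± 0.34) and the adhesion molecule Icam1 at 196 ± 28.9 CPM (6.40 ± 0.19). Of 23 immediate-early genes 16 rose and 4 fell (17 and 4 when adjusted over the list alone). The mRNA-decay factor Zfp36 rose 798-fold to 2920 ± 2450 CPM and the antiproliferative gene Btg2 rose 76.1-fold, while the nuclear receptors Nr4a3 and Nr4a2 fell 61.8-fold and 46.9-fold. Immediate-early levels differed widely among the ex vivo libraries: Fos, a subunit of AP-1, stood at 5370, 566, 26.3, 2120 and 2010 CPM in replicates 1 to 5, and Egr1, a zinc-finger factor, at 9330, 710, 23.0, 7940 and 4400 CPM.

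Transcripts of neurons were depleted by the sort. Snhg11 and Meg3, long noncoding RNAs abundant in neurons, fell from 2300 ± 197 and 4990 ± 317 CPM to 0.0718 ± 0.0604 and 0.231 ± 0.219 CPM. The potassium channel gene Kcnf1 and the neuropeptide genes Sst and Penk had no counts in any ex vivo library, at least 4890-fold, 4080-fold and 2650-fold lower than in lysate against a floor of 3 counts over the group. All 10 neuron markers, all 9 astrocyte, 8 oligodendrocyte, 5 oligodendrocyte precursor and 6 mural markers, and 7 of 8 endothelial markers, were lower after sorting. Summed marker CPM ex vivo was 0.214% of lysate for neurons, 4.05% for astrocytes (80.2% of it the glutamate transporter Slc1a3), 2.20% for oligodendrocytes, 1.02% for oligodendrocyte precursors, 2.03% for mural cells and 17% for endothelium, of which 89.5% was Pecam1, an adhesion molecule that macrophages also express. Without ex vivo replicate 3 the neuron share was 0.133%. Blood markers varied between ex vivo libraries: S100a8, a neutrophil protein, stood at 35.7 and 43.8 CPM in replicates 2 and 3 and at 0.450 to 5.33 CPM in the other 3. The choroid plexus gene Ttr stood at 109 CPM in replicate 3, 34.0 in replicate 4 and under 10 CPM in the others. The erythroid list was at 4.48% of lysate, the choroid and ependymal list at 11.7%, the monocyte list at 35.6%, the T and NK cell list at 90.9% of a lysate level of only 0.0365 CPM, and the border macrophage list at 517%. The B cell list, 98.9% of it Cd79b, was at 2440% and the neutrophil list at 4510%. These shares rest on lysate levels of only 0.123 and 0.247 CPM per gene, against 3.00 and 11.1 CPM ex vivo. The lysate level of the border macrophage list was 1.47 CPM. Of 5 B cell markers only 1 had enough counts to be tested, and it was higher after sorting. Without replicate 3 the erythroid share was 2.82%, the choroid and ependymal share 4.63%, the T and NK cell share 28.7% and the border macrophage share 372%. Without replicate 2 the monocyte share was 23.9% and the neutrophil share 3110%.

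**Figure D1:**
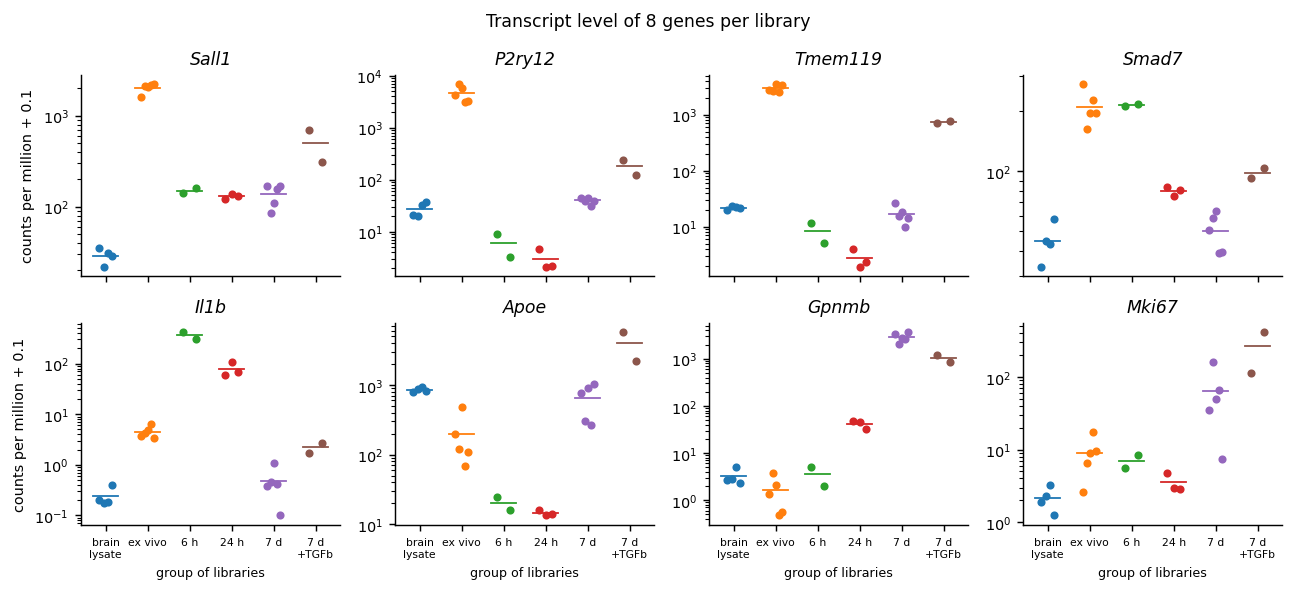
CPM (log axis, 0.1 added) of 8 genes in each of the 21 RNA libraries, by group; points are libraries and bars are group means. P2ry12 stood at 4410 CPM ex vivo, 7.65 at 6 h, 2.66 at 24 h and 39.5 at 7 d, and at 194 with TGFβ.

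Culture for 6 h (n = 2), the earliest time measured, was compared with ex vivo cells (n = 5). Ex vivo cells had already been isolated and culture added serum and IL-34, so changes cannot be assigned to leaving the brain. P2ry12 fell 572-fold, from 4410 ± 1510 to 7.65 ± 5.21 CPM (-9.16 ± 0.67, adjusted p = 5.01e-09), and Tmem119 fell 271-fold (-8.08 ± 0.55). Sall1 fell 10.2-fold (-3.35 ± 0.36), Cx3cr1 10.5-fold (-3.39 ± 0.27), Csf1r 5.21-fold (-2.38 ± 0.17) and Apoe 7.16-fold (-2.84 ± 0.78), whereas Spi1 rose 3.18-fold (1.67 ± 0.16). Il1b rose 109-fold, from 4.19 ± 1.06 to 453 ± 108 CPM (6.77 ± 0.38). Mki67 stood at 8.63 ± 2.43 against 8.45 ± 5.27 CPM and was not called. Of 24 homeostatic genes 22 fell, including P2ry13, a purinergic receptor (-8.58 ± 0.52), the fructose transporter Slc2a5 (-9.10 ± 0.76), the lysophosphatidylserine receptor Gpr34 (-8.56 ± 0.87), Selplg, a selectin ligand (-5.85 ± 0.25), and the secreted protein Olfml3 (-6.33 ± 0.46). The TGFβ receptor Tgfbr1 (2350 ± 582 against 2780 ± 707 CPM) and the endocytic adaptor Bin1 (645 ± 131 against 748 ± 122 CPM) were not called, though Bin1 was with the deposited TPM (-0.54, adjusted p = 0.00605). Tlr12, a toll-like receptor, fell from 87.0 ± 16.2 to 0.207 ± 0.130 CPM.

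Inflammatory genes moved the other way at 6 h, with 19 of 23 higher and none lower. Ptgs2, the inducible cyclooxygenase, rose from 1.86 ± 1.65 to 2580 ± 196 CPM (10.46 ± 0.75), the neutrophil chemokine gene Cxcl2 from 0.339 ± 0.411 to 543 ± 16.2 CPM (10.69 ± 0.93), Cd14 15.1-fold (3.92 ± 0.20) and the activation marker Cd83 14.5-fold (3.86 ± 0.26). The largest rises were in Lrrc32, a carrier of latent TGFβ (289 ± 25.3 CPM, 12.27 ± 0.34), the fusion protein Dcstamp (183 ± 11.4 CPM, 11.62 ± 0.39), filamin C (Flnc, 11.18 ± 0.43) and the adhesion molecule Esam (71.2 ± 17.6 CPM against 3 counts in 5 libraries, a ratio of 766 to 10800). Among 27 microglial transcription factors 10 rose and 9 fell: Mitf, a regulator of lysosomal genes, rose 4.23-fold (2.08 ± 0.19), and the lineage factors Ikzf1 and Irf8 fell 7.89-fold (-2.98 ± 0.18) and 4.26-fold (-2.09 ± 0.17). Of 23 immediate-early genes 7 rose and 4 fell, beside the wide ex vivo spread given above. Nr4a3 rose 22.3-fold (4.48 ± 0.46), Maff 11.6-fold (3.53 ± 0.77), the AP-1 gene Fosl2 4.76-fold (2.25 ± 0.27) and Klf6 3.97-fold (1.99 ± 0.45).

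At 6 h, 4312 genes were higher and 5099 lower of 13840 tested; with the deposited TPM the split was 3089 and 5732. Apoe was not called without 6 h replicate 2 (-2.53, adjusted p = 0.0605). Smad7 (270 ± 3.70 against 201 ± 46.1 CPM, 0.42 ± 0.20) was called higher without ex vivo replicate 1 (0.58, adjusted p = 0.00770) and by DESeq2 (0.49, adjusted p = 0.0307). The homeostatic list passed camera (adjusted p = 5.57e-08), with adjusted p = 0.196 with an estimated correlation; across the 8 comparisons 52 of 104 list tests passed with the preset correlation and 0 held with an estimated one.

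After 24 h (n = 3 against 5 ex vivo libraries) the homeostatic list had fallen as a whole, 24 of 24 genes. P2ry12 was 1650-fold lower, at 2.66 ± 1.39 CPM (-10.69 ± 0.59, adjusted p = 2.17e-10), Tmem119 1140-fold lower (-10.16 ± 0.50), Sall1 16.0-fold (-4.0 ± 0.32), Cx3cr1 15.5-fold (-3.95 ± 0.23), Csf1r 5.46-fold (-2.45 ± 0.15) and Apoe 13.5-fold (-3.76 ± 0.69). The adhesion receptor Adgrg1 fell 315-fold (-8.30 ± 0.42), P2ry13 317-fold (-8.31 ± 0.42), Selplg 69.1-fold (-6.11 ± 0.21) and Gpr34 1410-fold (-10.46 ± 0.79). Smad7 fell 2.73-fold (-1.45 ± 0.18), Spi1 rose 1.79-fold (0.84 ± 0.15) and Il1b was 17.4-fold higher than ex vivo (4.12 ± 0.34). Mki67 stood at 3.18 ± 1.02 against 8.45 ± 5.27 CPM and was not called. The collagen gene Col6a3 had 1 count in 3 libraries against 76.2 ± 33.3 CPM ex vivo, a ratio of 960 to 211000, and the transporter Slco2b1 and the uroplakin Upk1b fell 2440-fold and 1450-fold.

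Cholesterol synthesis genes were higher at 24 h, 17 of 20, with 1 lower. The sterol demethylase Cyp51 rose 15.5-fold (3.95 ± 0.32) and the sterol regulator Srebf2 7.11-fold (2.83 ± 0.17). Nsdhl (18.3 ± 0.315 against 15.7 ± 1.43 CPM) and Mvk (5.64 ± 1.45 against 5.57 ± 1.66 CPM), enzymes of the same pathway, were not called. The largest rises were in macrophage elastase (Mmp12, 1.46 ± 1.12 to 7010 ± 876 CPM, 12.14 ± 0.60), Dcstamp (11.28 ± 0.38), the adhesion protein Flrt2 (10.57 ± 0.57), Lrrc32 (10.46 ± 0.33) and Spic, a relative of PU.1 (27.8 ± 11.3 CPM against 2 counts in 5 libraries, a ratio of 362 to 10800). Interferon-response genes were higher for 15 of 21 members, with Rsad2, an antiviral enzyme, at 43.3 ± 53.2 CPM (4.70 ± 0.83), Isg15, a ubiquitin-like modifier, at 14.6 ± 15.4 CPM (3.37 ± 0.68) and the DNA sensor Ifi204 at 82.2 ± 59.9 CPM (3.79 ± 0.38). Replicate 1 stood above the other 2: Ifit1, an RNA-binding effector, was at 110 CPM in it and at 7.70 and 14.4 CPM in the others, against at most 4.05 CPM in any ex vivo library. Without it Rsad2 (2.97), Isg15 (2.06) and Ifi204 (3.04) were still called, while the list, which passed camera with all libraries (adjusted p = 0.0198, 0.804 with an estimated correlation), did not pass (adjusted p = 0.220). In all, 4102 genes were higher and 4586 lower at 24 h.

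**Figure D2:**
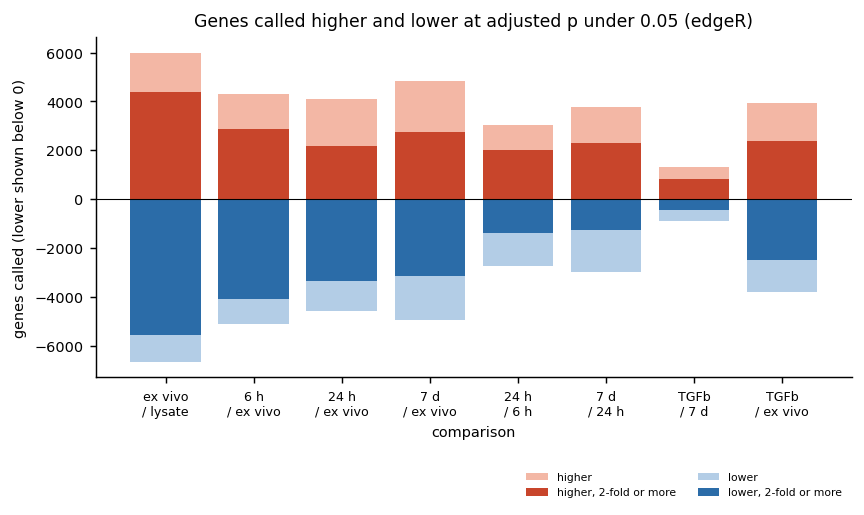
Number of genes called higher (upward) and lower (downward) in each of the 8 RNA comparisons at an adjusted p under 0.05, with those of at least 2-fold in the darker shade. With TGFβ against without, 1325 genes were higher and 902 lower, fewer than in any other comparison.

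After 7 d in IL-34 (n = 5 against 5) homeostatic genes were still low, while genes of phagocytosis, lysosomes and lipid handling were high. P2ry12 stood 111-fold below ex vivo cells, at 39.5 ± 6.15 CPM (-6.80 ± 0.39, adjusted p = 2.80e-10), Tmem119 169-fold below (-7.40 ± 0.34), Sall1 13.8-fold (-3.79 ± 0.25), Cx3cr1 9.32-fold (-3.22 ± 0.18), Csf1r 6.68-fold (-2.74 ± 0.12) and Smad7 4.08-fold (-2.03 ± 0.16). Of the 24 genes 23 fell, among them Siglech (1050-fold, -10.03 ± 0.41), Adgrg1 (106-fold) and Selplg (19.6-fold). The lipid receptor Trem2 (882 ± 214 against 664 ± 162 CPM) was not called by edgeR with all libraries, but was called higher without ex vivo replicate 3 (0.54, adjusted p = 0.0104), 7 d replicate 1 (0.49, adjusted p = 0.0303) or 7 d replicate 4 (0.49, adjusted p = 0.0330). Spi1 was 1.38-fold higher (0.46 ± 0.13; not called with the deposited TPM, adjusted p = 0.0735), Apoe 3.63-fold higher (1.86 ± 0.51) and Mki67 7.36-fold higher (2.88 ± 0.65), and Il1b had fallen 10.7-fold below its ex vivo level (-3.42 ± 0.41). In all, 4821 genes were higher and 4943 lower; with the deposited TPM and no filter on low values the split was 3886 and 6112.

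Of 25 phagocyte, lysosome and lipid genes 22 rose by 7 d and 1 fell. The cathepsin Ctsb reached 23900 ± 3290 CPM (10.6-fold, 3.41 ± 0.14), lipoprotein lipase (Lpl) 10200 ± 579 CPM (326-fold, 8.35 ± 0.36), the lipid-droplet protein Plin2 2870 ± 232 CPM (151-fold, 7.24 ± 0.19) and the galectin Lgals3 1880 ± 263 CPM (576-fold, 9.17 ± 0.37). Gpnmb, a lysosomal glycoprotein, rose from 1.43 ± 1.23 to 2880 ± 718 CPM (10.96 ± 0.56), the largest rise by the rule used, ahead of the proton pump subunit Atp6v0d2 (10.62 ± 0.60), Mmp12 (10.38 ± 0.56), the lectin receptor Clec4d (10.22 ± 0.62) and the collagenase Mmp13 (9.92 ± 0.46). All 20 cholesterol synthesis genes rose, with the prenyl synthase Fdps at 11.5-fold (3.52 ± 0.26), Srebf2 at 5.24-fold and squalene synthase (Fdft1) at 5.21-fold. Proliferation genes rose for 23 of 25 members, with the replication helicase subunits Mcm6 and Mcm2 at 8.69-fold (3.12 ± 0.40) and 5.86-fold (2.55 ± 0.43), the kinesin Cenpe at 13-fold and survivin (Birc5) at 11.7-fold. Their mean log2 CPM was 3.07, 5.43, 4.25, 3.85 and 1.79 in replicates 1 to 5, the last inside the ex vivo range of 1.37 to 2.12. Over all genes replicates 2 and 3 stood apart, correlating at 0.992 with each other and at 0.945 to 0.972 with the other 3, which correlated at 0.981 to 0.992; without both, 4425 genes were higher and 4792 lower at 7 d. Thymidylate synthase (Tyms, 6.43 ± 5.67 against 4.54 ± 0.394 CPM) was not called.

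Interferon-response genes rose for 18 of 21 members at 7 d. Ifi204 rose 37.5-fold (5.23 ± 0.38), Isg15 14.7-fold (3.88 ± 0.65), the viral tether Bst2 6.41-fold (2.68 ± 0.38) and Stat2 3.78-fold (1.92 ± 0.32). The mean log2 CPM of this list was 5.75, 6.28, 6.41 and 6.27 in replicates 1 to 4 and 4.22 in replicate 5. Immediate-early genes fell for 18 of 23 members from their uneven ex vivo levels, with Btg2 39.9-fold (-5.32 ± 0.61), Zfp36 17-fold (-4.09 ± 0.57), Junb 16.2-fold (-4.02 ± 0.60) and Egr3 82.7-fold (-6.37 ± 0.96) lower. Klf6 (509 ± 57.8 against 575 ± 425 CPM) and the stress factor Atf3 (306 ± 44.6 against 398 ± 491 CPM) were not called. The largest falls included the inducible heat-shock genes Hspa1b (-10.33 ± 0.97) and Hspa1a (-10.02 ± 1.16), near-identical paralogs whose counts cannot be assigned with certainty and which were uneven ex vivo (Hspa1a at 720, 77.6, 5.89, 403 and 559 CPM), and Upk1b (-9.94 ± 0.38). Ttr also fell (-9.60 ± 1.84), from ex vivo levels of 0.748 to 109 CPM. Camera passed the lists of phagocyte genes (adjusted p = 4.25e-09, 0.149 with an estimated correlation), cholesterol synthesis (1.11e-07, and adjusted p = 0.345 with an estimated correlation) and proliferation (7.98e-04, and adjusted p = 0.730 with an estimated correlation).

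Between 6 h (n = 2) and 24 h (n = 3) most cholesterol synthesis genes rose and a part of the inflammatory genes fell. Of 20 cholesterol genes 19 rose and none fell, including Cyp51 (21.4-fold, 4.42 ± 0.48), the reductase Dhcr7 (14.7-fold, 3.88 ± 0.32), the sterol carrier Stard4 (14.2-fold, 3.83 ± 0.51) and Mvk (11.5-fold, 3.52 ± 0.46), with Fdft1 at 82.2 ± 6.68 against 59.1 ± 3.76 CPM not called by edgeR but called with the deposited TPM (0.80, adjusted p = 0.00942). Of 23 inflammatory genes 11 fell and 1 rose. Il1a fell 12.0-fold (-3.59 ± 0.47), Il1b 6.28-fold (-2.65 ± 0.40), Icam1 4.41-fold (-2.14 ± 0.21) and Cd83 3.48-fold (-1.80 ± 0.30), and the chemokine genes Ccl3 (1070 ± 66.0 against 1760 ± 23.0 CPM) and Ccl4 (514 ± 47.4 against 1180 ± 126 CPM) were not called. Tmem119 fell a further 4.26-fold, Smad7 3.66-fold and Spi1 1.78-fold. Sall1 (120 ± 6.90 against 189 ± 11.7 CPM), Csf1r (2180 ± 319 against 2290 ± 58.7), Apoe (13.3 ± 1.49 against 25.1 ± 7.99) and Mki67 (3.18 ± 1.02 against 8.63 ± 2.43) were not called.

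The largest rises of this step were in the dipeptidase Dpep2 (137-fold, 7.10 ± 0.57), the lectin receptors Clec4a3 (26.4-fold) and Clec4a2 (19.8-fold), Cyp51 and Creg2 (19.0-fold). Nephronectin (Npnt, 81.6-fold, -6.35 ± 0.73), Slco2b1 (67.2-fold), Csmd3 (39.4-fold), Fam83g (35.0-fold) and Siglech (34.3-fold) fell most. P2ry12 fell 2.89-fold (-1.53 ± 0.48, adjusted p = 0.0171) and missed the call without 24 h replicate 2 (-1.32, adjusted p = 0.0650), 24 h replicate 3 (-1.3, adjusted p = 0.0674) or 6 h replicate 1 (-0.58, adjusted p = 0.479) and with the deposited TPM (-0.82, adjusted p = 0.116), while Cx3cr1 (580 ± 98.5 against 857 ± 96.5 CPM) was called lower without 24 h replicate 1 (-0.69, adjusted p = 0.0497) and by DESeq2 (-0.66, adjusted p = 0.0156). In all, 3045 genes rose and 2734 fell, against 1848 and 1767 without 6 h replicate 1. The deposited TPM gave 4330 and 1475, its median over all genes lying 0.21 higher. With DESeq2 size factors the balance turned, to 2696 and 3135, and with the DESeq2 test to 2876 and 3294.

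From 24 h (n = 3) to 7 d (n = 5) inflammatory transcripts fell further, and a part of the homeostatic list came up from its low point. Il1b fell 185-fold to 0.377 ± 0.338 CPM (-7.53 ± 0.42, adjusted p = 2.87e-09), Cxcl2 117-fold (-6.87 ± 0.74), Il1a 38.1-fold (-5.25 ± 0.41) and Nlrp3 4.66-fold (-2.22 ± 0.27). Of 23 inflammatory genes 17 fell (18 when adjusted over the list alone) and 1 rose, with Ccl3 (409 ± 116 against 1070 ± 66.0 CPM) and Ccl4 (307 ± 154 against 514 ± 47.4 CPM) not called. P2ry12 rose 14.8-fold (3.89 ± 0.44), Tmem119 6.77-fold (2.76 ± 0.36) and Cx3cr1 1.66-fold (0.73 ± 0.20), whereas Sall1 stood at 139 ± 42.8 against 120 ± 6.90 CPM and was not called. Targets of the sterol receptor LXR rose for 7 of 11 members and none fell: Apoe 49.2-fold (5.62 ± 0.76), the desaturase Scd2 8.75-fold (3.13 ± 0.56), Smpdl3a 7.16-fold (2.84 ± 0.18) and the phospholipid transfer protein Pltp 3.61-fold (1.85 ± 0.37). The ubiquitin ligase Mylip (87.5 ± 20.4 against 97.0 ± 3.26 CPM), and the acyltransferase Lpcat3 (87.2 ± 7.92 against 73.6 ± 6.33 CPM) were not called. Mki67 rose 19.4-fold (4.28 ± 0.87) and Smad7 fell 1.49-fold (-0.58 ± 0.17).

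The cytoskeletal linker talin 2 (Tln2, 437-fold, 8.77 ± 0.28), Asb10 (300-fold), the IGF-binding protein Igfbp4 (296-fold), Wfdc17 (242-fold) and the glutaminyl cyclase Qpct (215-fold) rose most from 24 h to 7 d. Dcstamp (357-fold, -8.48 ± 0.30), Lrrc32 (333-fold, -8.38 ± 0.27) and the lipid-sensing receptor Gpr132 (199-fold) fell most beside Il1b and Cxcl2. Spi1 was 1.30-fold lower (-0.38 ± 0.15, adjusted p = 0.0429), and this call was lost, with changes of like size, without any 1 of the 3 24 h libraries (-0.42, -0.34 and -0.45, adjusted p = 0.0749, 0.130 and 0.0573 without replicates 1 to 3) or without 7 d replicate 1, 2, 3 or 5 (-0.35, -0.37, -0.39 and -0.36, adjusted p = 0.0829, 0.0724, 0.0570 and 0.0718). Csf1r (1780 ± 116 against 2180 ± 319 CPM) was not called by edgeR with all libraries, and was called lower without 24 h replicate 3 (-0.42, adjusted p = 0.0378), by DESeq2 (-0.32, adjusted p = 0.00886) and with the deposited TPM (-0.47, adjusted p = 0.00203). In all, 3769 genes rose and 2985 fell, and the deposited TPM gave 2632 and 3814, with a median over all genes 0.12 lower.

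Changes at the 3 culture times largely ran the same way. Of 13840 genes, 8703 were called in 1 direction at 2 or more times, 4121 higher and 4582 lower, and 2256 were higher and 2598 lower at all 3. Between 6 h and 24 h, 3082 genes rose and 3602 fell at both times, where independent calls would give 1278 and 1690. The corresponding numbers were 2484 and 2851 for 6 h and 7 d (1502 and 1821 if independent) and 3067 and 3325 for 24 h and 7 d (1429 and 1638 if independent). All 3 contrasts share the ex vivo libraries. In 20 simulations of unchanged groups no gene was called at both times of any pair. As no gene was changed in them, this cannot show how many shared calls the ex vivo libraries add among changed genes. Simulated fold changes correlated at 0.322, 0.373 and 0.437 against 0.831, 0.535 and 0.734 in the data. Covariances were 4.25, 2.56 and 3.12 against simulated values of 0.062, 0.061 and 0.061. With the ex vivo libraries split so that no contrast shared one, the median total was 5903 (5696 to 6272), 4678 (4522 to 5022) and 5401 (5244 to 5865). Another 684 genes, Il1b among them, were higher at 6 h and lower at 7 d than ex vivo, and 829, Apoe among them, were lower at 6 h and higher at 7 d. The difference between the times was called for each. That adds no support, since the genes were chosen for opposite calls against the same ex vivo libraries.

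**Figure D3:**
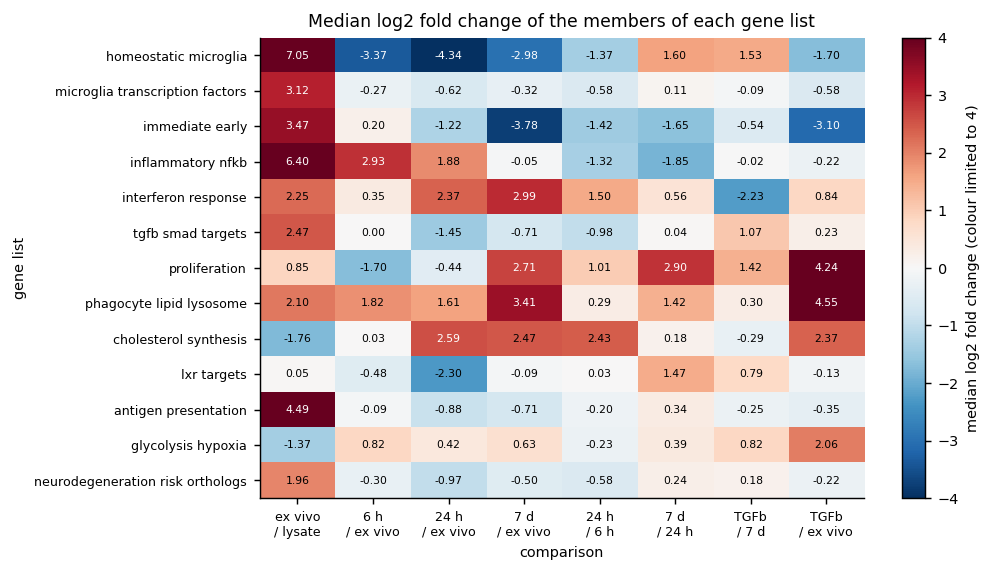
Median log2 fold change of 13 gene lists down the side, in 8 RNA comparisons along the base, coloured from negative to positive. The homeostatic list ran from 7.05 on sorting to -4.34 at 24 h and stood at 1.53 with TGFβ against 7 d without.

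Addition of TGFβ to the 7 d culture (n = 2 against 5 without) tested how far this cytokine maintained the ex vivo programme. Of 24 homeostatic genes 18 rose and none fell. Tmem119 rose 46.9-fold, from 16.7 ± 6.61 to 783 ± 5.91 CPM (5.55 ± 0.34, adjusted p = 9.93e-09), the matrix protein Sparc 47.2-fold (5.56 ± 0.36), Siglech 43.1-fold (5.43 ± 0.38) and Selplg 6.02-fold (2.59 ± 0.17). P2ry12 rose 4.92-fold (2.30 ± 0.38), Sall1 3.89-fold (1.96 ± 0.28), Cx3cr1 2.83-fold (1.50 ± 0.21) and Csf1r 2.07-fold (1.05 ± 0.14). Trem2 (715 ± 168 against 882 ± 214 CPM) and Spi1 (336 ± 27.2 against 331 ± 33.1 CPM) were not called. Targets of TGFβ and SMAD rose for 12 of 17 members and none fell: the matrix protein Tgfbi 49.5-fold (5.63 ± 0.53), the SMAD antagonist Pmepa1 9.85-fold (3.3 ± 0.30) and Bhlhe40, a transcriptional repressor, 4.79-fold (2.26 ± 0.29). Smad7 rose 2.10-fold (1.07 ± 0.19), while Tgfbr2 (751 ± 119 against 777 ± 117 CPM) and the integrin Itgav (622 ± 32.0 against 581 ± 83.1 CPM) were not called.

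Glycolysis and hypoxia genes rose with TGFβ for 11 of 18 members (14 when adjusted over the list alone). The oxygen-sensing hydroxylase Egln3 rose 36.0-fold (5.17 ± 0.41), phosphofructokinase Pfkl 2.60-fold (1.38 ± 0.17), the kinase Pdk1 2.27-fold (1.18 ± 0.17) and the glucose transporter Slc2a1 2.22-fold (1.15 ± 0.15), with Pkm (1730 ± 263 against 1290 ± 310 CPM) and Pfkfb3 (305 ± 48.9 against 319 ± 61.1 CPM) not called. Igfbp5 (88.6 ± 25.2 CPM, 9.14 ± 0.89), fibronectin (Fn1, 256 ± 45.2 CPM, 8.88 ± 0.79), the acyl-CoA synthetase Acsbg1 (26.7 ± 25.0 CPM, 8.84 ± 1.33), Notch4 (137-fold) and cystatin F (Cst7, 127-fold) rose most. Largest among the falls were the scavenger receptor Cd36 (44.3-fold, -5.47 ± 0.73), Emp1 (29.2-fold), the stress cytokine Gdf15 (20.8-fold), the dicarboxylate transporter Slc13a3 (20.4-fold) and the folate receptor Folr2 (16.2-fold). Interferon-response genes had a median log2 fold change of -2.23, but only Ifi204 of 21 was called lower over all genes (-2.08 ± 0.46), against 16 adjusted over the list alone. Without TGFβ replicate 1 or 2 the change was of like size but not called (-2.03 and -2.1, adjusted p = 0.0684 and 0.0589). Stat2 (100 ± 20.4 against 226 ± 54.9 CPM) was not called by edgeR with all libraries, and was called lower by DESeq2 (-1.14, adjusted p = 0.0269) and with the deposited TPM (-1.26, adjusted p = 0.0390).

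Apoe rose 6.50-fold with TGFβ (2.70 ± 0.61), to library values of 5700 and 2210 CPM from 269 to 1030 CPM without it. It was not called without TGFβ replicate 1 (1.80). Il1b rose 5.74-fold to 2.22 ± 0.618 CPM and was not called without TGFβ replicate 2 (2.22, adjusted p = 0.0555). Mki67, at 273 ± 209 against 61.6 ± 54.2 CPM, was not called by edgeR with all libraries (adjusted p = 0.0576) but was without 7 d replicate 2 (2.79, adjusted p = 0.0144), by DESeq2 (2.18, adjusted p = 0.0486) and with the deposited TPM (2.08, adjusted p = 0.0448). Of the marker lists, summed oligodendrocyte precursor markers reached 102% of lysate with TGFβ, 99.8% of it the proteoglycan Cspg4, and monocyte markers 300%, 99.3% of it Fn1. The precursor mean per gene differed between the TGFβ libraries, at 24.8 and 70.1 CPM, against a mean of 46.5 CPM in lysate. In all, 1325 genes rose and 902 fell. With the deposited TPM the numbers were 942 and 1547, the median over all genes lying 0.09 lower, and 411 and 375 genes fell without TGFβ replicate 1 and 2.

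Cells kept 7 d with TGFβ (n = 2) still differed from ex vivo cells (n = 5), and 3920 genes were higher and 3801 lower (3814 and 3942 with DESeq2 size factors and 3849 and 4084 with its test, more lower than higher; 2533 and 5197 with the deposited TPM, whose median lay 0.23 lower; 2393 lower without TGFβ replicate 2). Of 24 homeostatic genes 16 were lower and none higher: P2ry12 22.8-fold (-4.51 ± 0.53, adjusted p = 3.28e-06), Siglech 24.1-fold (-4.59 ± 0.48), Adgrg1 22.6-fold (-4.50 ± 0.41), P2ry13 12.6-fold (-3.66 ± 0.40), Tmem119 3.61-fold (-1.85 ± 0.38), Sall1 3.58-fold (-1.84 ± 0.33), Cx3cr1 3.29-fold (-1.72 ± 0.24) and Csf1r 3.23-fold (-1.69 ± 0.17). Sparc (2410 ± 1120 against 3050 ± 292 CPM) was not called. Smad7 was 1.95-fold lower (-0.96 ± 0.21), Apoe 23.4-fold higher (4.55 ± 0.62) and Il1b, at 2.22 ± 0.618 against 4.19 ± 1.06 CPM, not called by edgeR but called lower by DESeq2 (-0.94, adjusted p = 0.0354) and with the deposited TPM (-1.0, adjusted p = 0.00651). All 25 proliferation genes were higher, with Mki67 32.7-fold (5.03 ± 0.77), Cenpe 45.6-fold (5.51 ± 0.73), the anaphase activator Cdc20 27.3-fold (4.77 ± 0.64), Mcm6 12.6-fold (3.65 ± 0.46) and the mitotic kinase Aurka 12.0-fold (3.59 ± 0.52). The mean log2 CPM of this list differed between the TGFβ libraries, at 4.2 and 6.01, against 1.37 to 2.12 ex vivo. Spi1 was 1.39-fold higher (0.48 ± 0.17), a call lost without TGFβ replicate 1 (0.56, adjusted p = 0.0600), TGFβ replicate 2 (0.41, adjusted p = 0.179) or ex vivo replicate 4 (0.38, adjusted p = 0.0563) and with the deposited TPM (0.14, adjusted p = 0.467).

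The largest rises over ex vivo cells were in Ctla2a (10.05 ± 0.42), argininosuccinate synthase (Ass1, 9.95 ± 0.50), cholesterol 25-hydroxylase (Ch25h, 9.91 ± 0.72), osteopontin (Spp1, 2620 ± 1750 CPM, 9.85 ± 0.71) and the Apoc4-apoc2 locus (23.4 ± 6.25 CPM against 2 counts in 5 libraries, a ratio of 305 to 9090). The falls were led by Enpp2 and Ttr, choroid plexus transcripts with no counts with TGFβ, at least 481-fold and 461-fold lower than ex vivo. Ttr was not called without TGFβ replicate 1 or 2. Its ex vivo libraries ran from 0.748 to 109 CPM, highest in replicate 3, so the bound for Ttr depends on that library. Lactoferrin (Ltf), a neutrophil gene, had 1 count in 2 libraries against 21.4 ± 21.7 CPM ex vivo, a ratio of 193 to 42500, and Hspa1a and Hspa1b fell 962-fold and 771-fold from their uneven ex vivo levels.

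A part of the genes changed at 7 d differed in the opposite direction between 7 d cultures with and without TGFβ. They are called moved back below, a name for the direction only. Cells with and without TGFβ were cultured separately, so a change that was reversed cannot be told from one that never arose. No label gives a preparation, so an effect of TGFβ cannot be told from one of preparation. Of 4943 genes that had fallen at 7 d, 900 rose with TGFβ, and of 4821 that had risen, 646 fell, where independent calls would give 473 and 314. Another 211 and 97 genes moved further up and further down. Among the 900, 408 did not differ from ex vivo cells with TGFβ at the threshold, 409 remained lower and 83 were higher; among the 646 the numbers were 297, 321 and 28. Both contrasts use the 7 d libraries, and their fold changes correlated at -0.310 against -0.353 in simulations of unchanged groups, with a covariance of -0.681 against -0.056. Those simulations called 0 genes in both contrasts. No gene was changed in them, so the 0 cannot show how many opposite calls shared libraries give among changed genes. Splitting the 7 d libraries so that the contrasts shared none gave a median total of 1129 (835 to 1770) against 1546. The number that independent calls would give in the splits is not reported. Without TGFβ replicate 1 or 2 the total was 861 and 974.

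The ATAC and H3K27ac peak lists of ex vivo cells and 7 d overlapped in part. Of 90674 ATAC peaks ex vivo 68038 (75.0%) overlapped a 7 d peak, and of 112977 at 7 d 68007 (60.2%) overlapped an ex vivo peak; shifted peaks overlapped at 1.73% and 1.38%. For H3K27ac 16623 of 24520 peaks ex vivo (67.8%) and 18030 of 31349 at 7 d (57.5%) were shared, against 5.23% and 4.28%. The lists were made from pooled libraries, 23.8 and 15.2 M tags for ATAC and 45.6 and 27.6 M for H3K27ac, so no test between replicates was possible. A change at single sites cannot be told from a difference in what was called. ATAC peaks found in 1 list only stood late in file order, at a median place of 66597 against 37430.5 for shared ones ex vivo and 79052.5 against 41064 at 7 d. The files hold no score, and whether file order ranks the peaks by strength is not known. The share of tags in peaks also differed, 25.9% ex vivo and 37.1% at 7 d for ATAC and 64.0% and 32.1% for H3K27ac, whose peaks covered 61.3 and 50.9 Mb at a median width of 1777 and 1117 bp. Of the ATAC peaks found ex vivo only, 14.8% lay within 1 kb of a gene end, against 21.4% of shared ones and 7.3% of those found at 7 d only. PU.1, which was profiled ex vivo and not at 7 d, overlapped 58.1% of shared ATAC peaks, 35.6% of ex vivo-only and 13.6% of 7 d-only peaks.

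Around microglial genes H3K27ac peaks covered less sequence at 7 d, with more peaks at some genes and as many or fewer at others. Within 100 kb of P2ry12 (mm10 chromosome 3, 59216271 to 59262985) H3K27ac peaks covered 63.0 kb ex vivo and 26.0 kb at 7 d, in 7 and 13 peaks, with the longest at 39.9 and 6.6 kb. Near Tmem119 (chromosome 5, 113793729 to 113800396) they covered 71.0 and 21.7 kb in 7 and 13 peaks, near Sall1 (chromosome 8, 89027242 to 89044162) 31.2 and 15.2 kb (5 and 4 peaks), near Cx3cr1 66.8 and 45.4 kb (7 and 16 peaks), near Csf1r 46.3 and 29.0 kb (5 and 9), near Smad7 57.2 and 21.6 kb (18 and 10) and near Il1b 31.6 and 5.7 kb (8 and 8). Spi1 (46.7 and 43.3 kb) and Apoe (26.3 and 21.6 kb) differed less, and Mki67 went from 11.6 to 19.5 kb. Near the genes that rose most at 7 d the order was reversed: 2.6 and 17.8 kb for Gpnmb, 2.8 and 19.1 kb for Atp6v0d2, 1.4 and 19.4 kb for Mmp12, and no peak ex vivo against 15.8 kb for Clec4d. Cd36, which fell with TGFβ, had no H3K27ac peak ex vivo and 12 covering 23.1 kb at 7 d. The other genes of the largest falls with TGFβ did not all share this. Emp1 went from 1.7 to 11.4 kb, while Gdf15 (51.9 and 50.2 kb), Folr2 (24.0 and 24.0 kb) and Slc13a3 (21.5 and 15.7 kb) showed no gain.

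**Figure D4:**
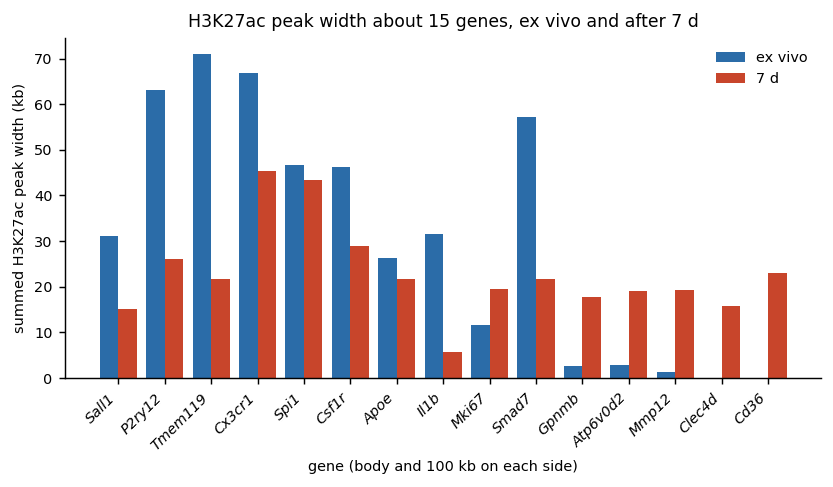
Summed width of H3K27ac peaks (kb) within 100 kb of 15 genes, ex vivo and after 7 d of culture; each bar is 1 pooled peak list, so no error can be shown. Tmem119 goes from 71.0 to 21.7 kb and Gpnmb from 2.6 to 17.8 kb.

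The direction of the 7 d change differed between genes near ex vivo-only and genes near 7 d-only peaks. Being called was itself common, for 70.5% of all 13840 genes tested (4943 lower and 4821 higher). The 2472 genes with more ex vivo-only than 7 d-only H3K27ac peaks had a median log2 fold change of -0.58 (7 d against ex vivo), and the 3254 genes with more 7 d-only peaks one of 0.39. The difference was -0.97 (95% bootstrap interval -1.06 to -0.89, 2-sided permutation p = 1e-05, the smallest that 100000 permutations can give); 1351 of the former fell and 516 rose, and 802 of the latter fell and 1596 rose. For ATAC the medians were -0.23 (2671 genes) and 0.13 (5399 genes), a difference of -0.36 (-0.44 to -0.29, permutation p = 1e-05). Genes are not independent replicates, and each peak was assigned to the nearest gene body within 100 kb.

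PU.1, the lineage factor of macrophages, had 79601 peaks ex vivo, of which 60.0% overlapped an ATAC peak, 45.8% an H3K4me2 peak and 41.5% an H3K27ac peak, against 1.43%, 3.37% and 2.90% for shifted peaks. All 3 were present at 24.2% and none at 25.9%. Peaks within 1 kb of a gene end, 16.5% of the total, overlapped all 3 at 55.4%, and the others at 18.1%. PU.1 also overlapped 89.5% of shared, 73.7% of ex vivo-only and 21.2% of 7 d-only H3K27ac peaks, classes with median widths of 2154, 1084 and 501 bp, against 8.74%, 4.94% and 3.28% for shifted PU.1 peaks. PU.1 was not profiled at 7 d, so its presence at 7 d-only peaks in cultured cells is not known.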

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

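In this part the tests of technical explanations were chosen after the result was seen, and only the counts of other splits were planned. Among 154 groups of 4 or 5 libraries searched for a library far from the rest, 11 stood out, where chance gives about 7.7.

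Immediate-early transcripts differed among the ex vivo libraries, with Fos at 5370, 2120 and 2010 CPM in replicates 1, 4 and 5 and at 566 and 26.3 CPM in replicates 2 and 3. RNA of another cell type in the high libraries is argued against, since the largest excess of any marker list was a mean of 0.556 CPM per gene (endothelium) beside a Fos difference of 2870 CPM. Depth is argued against by replicate 2 alone, which at 15.1 M counts (M, 1e6) lies inside the 13.3 to 21.4 M of the high libraries. Replicate 3, the lowest in Fos, held 21.9 M counts, above that range. Blood markers ran the other way, with neutrophil markers at 25.0 and 24.0 CPM per gene in replicates 2 and 3 against 0.440 to 5.41 in the others, and monocyte markers at 11.2 and 7.61 against 1.05 to 2.94. A difference in how the cells were prepared or sorted cannot be told apart from other causes: 69 genes outside the list were called between these sets, 35 higher and 34 lower, but no label gives a preparation and the sets were drawn from the pattern itself. An earlier version of that test asked for at least 100 genes called and would have argued against preparation with the 75 found; it was replaced after that count was seen, and no biological explanation was tested.

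The interferon-response list had a median log2 fold change of -2.23 with TGFβ and passed camera with the preset correlation (adjusted p = 1.91e-05) but not with an estimated one (0.600), with list means of 3.62 and 4.23 log2 CPM against 5.75, 6.28, 6.41, 6.27 and 4.22 without. Variation between 7 d cultures may account for it, since replicate 5 without TGFβ lies -0.01 from the higher library with it, and the next lowest lies 1.53 above. An effect of TGFβ stays open, as 1 of 21 members was called over all genes and 16 over the list alone, while the libraries without TGFβ spread from 4.22 to 6.41.

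Lists of precursor and monocyte markers were higher with TGFβ, through Cspg4 (124 and 350 CPM) and Fn1 (206 and 282 CPM). Cspg4 was also high without TGFβ at 6 h, at 72.4 and 80.2 CPM, against 0.225 to 0.745 CPM ex vivo. At 7 d without TGFβ it ran from 0.413 to 19.4 CPM. Fn1 was low at 6 h, at 1.09 and 0.935 CPM. RNA of oligodendrocyte precursors would need Pdgfra at 252 CPM by the lysate ratio, and 0 was observed; mural cells would need Pdgfrb at 131 CPM, and at most 0.209 was observed. Ccr2, Ly6c2 and Plac8 summed to at most 2.26 CPM with TGFβ and at least 3.21 without. This argues against monocytes that kept these transcripts, and cannot exclude cells that had lost them in culture. A candidate explanation is expression of Cspg4 and Fn1 by the cultured cells themselves, a hypothesis found and tested on the same libraries.

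Other libraries that lay far from their group are given as values, which are geometric means over the genes of the LXR and transcription factor lists and arithmetic means over marker genes. Ex vivo replicate 3 stood at 61.7 CPM on the LXR list (others 36.1 to 41.4), 27.9 on oligodendrocyte markers (11 to 14.4), 0.124 on T and NK cell markers (0 to 0.0245) and 0.767 on erythroid markers (0.115 to 0.253). Ex vivo replicate 2 stood at 4.77 CPM on endothelial markers (5.67 to 5.87), replicate 1 at 1590 for Sall1 (2050 to 2240) and replicate 4 at 0.975 for Spp1 (3.18 to 3.85). At 7 d, replicate 1 stood at 0.613 on monocyte markers (0.902 to 1.01), replicate 2 at 0.00522 on T and NK cell markers (others 0) and replicate 4 at 217 for Wfdc17 (140 to 158). Brain lysate replicate 4 stood at 27.1 on the microglial transcription factor list (24.1 to 24.6).

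The 33 genes examined for opposite changes were the 10 fixed ones and those of the largest changes at the 3 culture times; list members, such as Il1a, were not among them. Of these, 2 moved in opposite directions at 6 h and at 7 d relative to ex vivo cells, beside 684 and 829 genes of all those tested. The test of 7 d against 6 h gives the size of the difference. Its call was all but fixed by the choice of genes with opposite calls. Apoe was 4.70 ± 0.87 higher at 7 d than at 6 h on the log2 scale (edgeR adjusted p = 2.21e-04), and Il1b -10.18 ± 0.46 (adjusted p = 1.11e-10).

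The counts of genes called were set against other splits of the libraries in the 4 comparisons with at least 3 libraries per group. Each was fitted on its 2 groups, and no other split examined called as many genes as the real one. This argues against a chance assignment of independent libraries. No label gives an animal or a preparation, so a preparation shared within a group cannot be excluded. For ex vivo cells against lysate 1 of 100 splits drawn from 126, the real one, gave as many as 12675 genes, and the highest other, 8412, points to the structure of the samples, since it exchanged only 1 ex vivo library. For 24 h against ex vivo it was 1 of 56 (8191, highest other 20), for 7 d against ex vivo 1 of 100 drawn from 126 (8642, highest other 0) and for 7 d against 24 h 1 of 56 (6903, highest other 88).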

How the results depend on the processing

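Chosen after seeing the data were the tests without ex vivo replicates 2 and 3, without 7 d replicates 2 and 3, with peaks in file order, with peaks over 1 kb from a gene end, with the first part of the PU.1 list and with single libraries left out of the marker lists; the others were planned. Of these results under alternatives 321 values stayed and 46 moved, a count by over 1.5 times and a share of peaks beyond its 95% interval. Scaling with DESeq2 or its test, dropping or raising the low-count filter, fitting only the 2 groups and the replicate block left every count in the RNA comparisons within 1.5 times. The labels give no meaning to the replicate numbers. In the 4 comparisons with at least 3 shared numbers they show no pairing (same-number correlations of -0.094 to 0.101 for lysate, -0.141 to 0.012 for 24 h, -0.033 to 0.202 for 7 d and -0.037 to 0.068 for 7 d against 24 h), and not every sample correlates best with its own number. With only 2 shared numbers pairing cannot be judged: 0.227 and 0.235 for 24 h against 6 h (other pairs at most 0.026), 0.113 and 0.375 for TGFβ against 7 d (at most 0.418), -0.138 and -0.019 for 6 h and -0.023 and -0.007 for TGFβ against ex vivo. With the block 4825 genes were higher and 4933 lower at 7 d, 2897 and 2554 from 6 h to 24 h and 1216 and 823 with TGFβ against without, 50 list calls were made against 52, and 267 of 272 named values kept their call, all but Nr4a1 on sorting, Trem2 at 7 d, Stat2 with TGFβ against without, and Spi1 from 24 h to 7 d and with TGFβ against ex vivo.

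A fold change of at least 2, which keeps fewer genes by construction, left 2852 genes higher at 6 h, 2167 at 24 h and 2749 at 7 d, and 3132 lower at 7 d. It left 1994 higher and 1398 lower between 6 h and 24 h, 2276 and 1248 between 24 h and 7 d, 818 and 431 with TGFβ against without, 2366 and 2517 with TGFβ against ex vivo, 791 moved back by TGFβ and 5390 changed at more than 1 time. The deposited TPM with pseudocounts of 1 and 0.1 and without a filter gave 1475, 1427 and 1601 genes lower from 6 h to 24 h, and 4589 higher with 0.1; 1547, 1546 and 1391 lower with TGFβ against without; and 2533, 2559 and 2592 higher with TGFβ against ex vivo; the cause was not tested.

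Leaving out 1 library, with fewer samples by construction, gave 1848 to 2806 genes higher and 1767 to 2288 lower from 6 h to 24 h (lowest without 6 h replicate 1). It gave 375 to 891 lower with TGFβ against without and 2393 to 3794 lower against ex vivo (lowest without TGFβ replicate 2), and 861 to 1718 moved back (lowest without TGFβ replicate 1). Where 1 library was left in a group, it was assumed to vary like the others. With an estimated correlation 0 of the 52 list calls held (lowest adjusted p = 0.113), and fry called 68. Of 272 named values, 263 kept their call with DESeq2, and 2078 of 2117 with 1 library left out.

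Peak overlap moved with its definition; the cause was not tested. In order of reciprocal overlap of 50%, equal numbers in file order and the first part of each list against the first part of the other, ATAC peaks were shared at 72.2%, 67.8% and 74.7% ex vivo and 57.9%, 67.7% and 59.9% at 7 d. H3K27ac peaks were shared at 46.7%, 66.6% and 78.3% ex vivo and 36.5%, 71.7% and 65.5% at 7 d, and PU.1 peaks overlapped all 3 marks at 39.8% in the first part of the list and 22.0% with reciprocal overlap. The first part of each list against the whole of the other, also chosen after seeing the data, gave 88.9% and 78.6% for ATAC and 88.6% and 83.5% for H3K27ac (ex vivo and 7 d). The difference in expression near peaks ranged from -0.41 to -0.33 for ATAC and from -1.16 to -0.95 for H3K27ac. Equal numbers and the top of each list by score were not run because the files hold no score, nor were the motif alternatives without a genome. Whether file order, used in their place, ranks the peaks is not known. Depth limits the size of the largest falls: Kcnf1, with 0 counts ex vivo, can only be given as at least 4890-fold lower. In the simulations 2-fold changes were recovered at 35.8% with TGFβ against without, and depth was not varied.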

Other observations

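In this part no test was planned for the observation itself; the lists were fixed before, and the genes named were chosen after their values were seen. Of 18 antigen presentation genes 5 were higher and 10 lower after 7 d of culture (n = 5 against 5 ex vivo). Among those that fell were H2-Aa, a class II chain (log2 fold change -5.71 ± 1.07), the invariant chain Cd74 (-2.98 ± 0.64) and the peptide-loading chain H2-DMa (-3.67 ± 0.16), and the costimulatory ligands Cd86 (-1.92 ± 0.28) and Cd80 (-2.51 ± 0.22). The class I genes H2-D1 (2.01 ± 0.19) and H2-K1 (1.09 ± 0.24) and their partner B2m (1.41 ± 0.26, edgeR adjusted p = 1.43e-04) rose; no list of either class was fixed and no difference between the classes was tested. With TGFβ (n = 2), H2-DMa was 3.52 ± 0.18 higher than without, reaching 72.0 CPM against 80.2 ex vivo, and H2-Ab1 3.00 ± 0.68 higher, while H2-Aa stood at 0.0811 against 0.224 CPM and was not called. The list as a whole was not called by camera at 7 d (adjusted p = 0.342).

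Mouse orthologs of genes linked to human neurodegenerative disease fell more often than they rose at 24 h, 16 and 7 of 28. Rin3, a Rab5 regulator, fell (-3.04 ± 0.16), as did Abi3, an actin regulator (-3.54 ± 0.26), the phosphatase Inpp5d (-2.43 ± 0.18), the sialic acid receptor Cd33 (-2.96 ± 0.32) and the progranulin gene Grn (-1.06 ± 0.14). The γ-secretase gene Psen2 rose (2.54 ± 0.12). With TGFβ at 7 d, Cd33 was 2.23 ± 0.30 and Bin1 1.12 ± 0.16 higher than without. Camera did not call this list at 24 h (adjusted p = 0.198) and called it higher with TGFβ than without (0.0300), though not with an estimated correlation.

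The mean over 8 border macrophage markers was 7.60 ± 5.69 CPM per gene ex vivo (n = 5, 61.8% Mrc1), 0.455 at 6 h, 33.0 ± 12.2 at 7 d (n = 5, 69.7% Siglec1) and 31.2 ± 19.0 with TGFβ (n = 2, 96.6% Siglec1). For 8 neutrophil markers the mean per gene was 11.1 ± 12.3 CPM ex vivo and 0.275 ± 0.185 at 7 d. Brain lysate replicate 2 held 623 CPM of Xist, the X-inactivation RNA of female cells, and every other RNA library at most 1.39 CPM.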
